A study of Mus musculus with 9 samples.

How the data were processed

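The data are from mouse bone marrow mononuclear cells transduced with MLL-AF9 or with empty retroviruses. Groups were taken from the sample labels: 3 control and 3 MLL-AF9 polyA RNA libraries, 1 control and 1 MLL-AF9 library of 5hmC-enriched DNA, and 1 control input library, which was not analysed here. The labels' protocols describe unstranded TruSeq RNA libraries and single reads of 51 bp. They speak of duplicates per genotype for RNA, although 3 RNA samples per group are listed, so the pooled values and q-values may not rest on all 3. They name an antibody against methylated cytidine for the 5hmC samples, whereas the series' design text states selective chemical labelling. The labels do not say whether replicates came from separate animals.

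Per the submitters' processing notes, CASAVA 1.8.2, Bowtie 0.17.2, MACS 1.4, TopHat 1.4.1 and Cufflinks 1.3.0 were used with mouse build mm9. The role, order and settings of each are not given in the sources used here. The deposited RNA table holds 22942 rows with 1 value per group, taken as FPKM made by the authors, since the unit is not in the header and was inferred from the tools and the values. A p-value and a q-value per row come from the authors' own comparison, whose test is not stated per the file headers. Of the rows, 1134 are assembled loci without a gene name, and 5363 are listed at 0 in both groups. The deposited 5hmC files list regions per library with a score made by the authors, whose meaning is not stated. It was used to rank, filter and describe regions within a list, including medians, a ratio of medians and multiples of the lowest score of the same list, and in 1 named alternative as a floor common to both lists.

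The design fixed before the data were examined called for limma on values per library, for camera on gene lists, and for no test if the table held only a value per group. The last case applied. Genes were called from the authors' q-value under 0.05 with a mean of the 2 groups of at least 1 FPKM. No test of expression was computed anew from the values. S100a9 was left out as a failed estimate, since it is listed at 0 in control with a p-value of 1. Log2 changes are log2 of (FPKM + 1) in MLL-AF9 over control, which understates the change of low genes. Fold differences are ratios of the FPKM values, and none is given against a group listed at 0.

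The 23 gene lists fixed before the data were examined hold 377 members, of which 354 were matched by symbol, 2 of them through an alias. For each list the text gives the called members, the number passing after Benjamini-Hochberg adjustment of the authors' p-values over the list alone, and the percentile of its median log2 change among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was taken as shifted below percentile 2.5 or above 97.5. The percentile describes these pooled values and is not a test over replicates. The step was tested on simulated data from the 11538 expressed genes with lists of 14 genes: 3 of 100 lists without a shift lay outside these limits, and 79 of 100 with an added shift of 0.5 and 100 of 100 with a shift of 1 did. The simulation drew members independently, after changes were permuted over genes, with fewer random lists per percentile. Members of a real list can move together, so 3 of 100 is no error rate for the lists reported.

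The rule for named genes, also fixed beforehand, took Tet1, Tet2, Tet3, Hoxa9, Hoxa10, Meis1, Pbx3, Mll1 and Mllt3 in any case, up to 3 called members of each list with the smallest q-value, and the 6 largest rises and 6 largest falls among called genes with at least 5 FPKM in the higher group. Its condition that the groups' values do not overlap needs values per library and was not applied. For 5hmC it took the 3 regions of the highest score per library without an overlap. Other genes are named as members of fixed lists, to describe a list, and were chosen after their values were seen. Some genes that the rule takes are not reported here.

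Regions were compared with bedtools 2.31.1, with at least 1 bp counted as an overlap and coordinates given from 1 in mm9. Overlaps were set against 100 shuffles within chromosomes, and distances against 1 shuffle. Wilson intervals of shares cover counting error only. The annotation used here is of build GRCm38, so regions were not assigned to genes, and the planned comparison of expression with 5hmC by gene was not run. Alternatives were other pseudocounts, filters and scalings for RNA, and other overlaps, thresholds and merging for 5hmC. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.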

Results

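The series profiled mouse bone marrow mononuclear cells of the B6.SJL strain, which carries the CD45.1 marker. Cells had received retroviruses carrying MLL-AF9, the leukemia fusion of the histone methyltransferase MLL with AF9, or the matching empty viruses (control). PolyA RNA was sequenced from 3 libraries per group. 5-Hydroxymethylcytosine (5hmC), the oxidation product of methylated cytosine made by TET enzymes, was profiled in 1 library per group. The series' design text states selective chemical labelling for it, whereas the labels name an antibody against methylated cytidine. The remaining sample of the 9, an input DNA library of control cells, was not analysed here. For RNA the authors' deposited table gave 1 pooled FPKM value per gene and group with their p-value and q-value, so spread between libraries and depth are unknown, and no error of its own can stand beside an expression value. Which of the 3 libraries per group entered the pooled values is not known. The 5hmC lists have no replicates.

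The first comparison asked how gene expression differed between MLL-AF9 and control cells. Of the fixed lists, the largest rise was in the Hoxa cluster and its partner genes, and the broadest falls were in genes of mature granulocytes, eosinophils, red cells and lymphocytes. Of 11538 genes with a mean of at least 1 FPKM, 1192 had a q-value under 0.05 in the authors' deposited table. Of these, 592 were higher and 600 lower in MLL-AF9 cells. A change of at least 2-fold, on the log2(FPKM + 1) scale used for log2 changes throughout, was seen for 537 of the higher and 587 of the lower genes. The median expressed gene was shifted upward by 0.29 on this scale, and the list medians below are to be read against that shift.

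Hoxa genes, transcription factors of body patterning and blood progenitors, rose. Of 19 matched Hox genes 10 reached a mean of 1 FPKM, the Hoxa genes among them by their MLL-AF9 values alone. Of these 10, 9 rose, 0 fell and 9 passed when adjusted over the list alone. The median log2 change was 3.97, at percentile 100 of 10000 random lists matched on mean expression, and 6.09 with a pseudocount of 0.1. Hoxa9 stood at 65.9 FPKM in MLL-AF9 and 0.876 in control cells, a 75.3-fold difference with q = 1.26e-12 in the authors' deposited table. Hoxa10 was 219-fold higher, at 51.3 against 0.235 FPKM, and Hoxa5 was 91.0-fold higher, at 45.8 against 0.503 FPKM. The 9 that rose were all Hoxa genes, and the remaining member, Hoxb4, was listed at 1.97 against 3.76 FPKM with q = 0.571 in the authors' deposited table. The 9 genes under that mean were not counted, among them Hoxb3, at 0.488 against 1.06 FPKM, and Hoxb2, at 0 against 0.376 FPKM. Neighbouring and antisense transcripts of the cluster could not be separated, because the library kit does not keep strand.

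Among 19 expressed MLL-fusion targets, 18 rose, 0 fell and 18 passed when adjusted over the list alone, with a median log2 change of 4.02 at percentile 100. This list shares 5 Hoxa genes with the Hox list. Meis1, a homeodomain cofactor of Hoxa9, rose 25.3-fold from 1.68 to 42.6 FPKM, and Pbx3, another cofactor, rose 5.84-fold from 2.30 to 13.4 FPKM (q = 0.00678 in the authors' deposited table). The transcriptional coactivator Eya1 rose from 0.534 to 27.8 FPKM and the receptor kinase Flt3 from 5.75 to 160 FPKM. Id2 was the member that did not pass, at 111 against 82.7 FPKM.

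**Figure D1:**
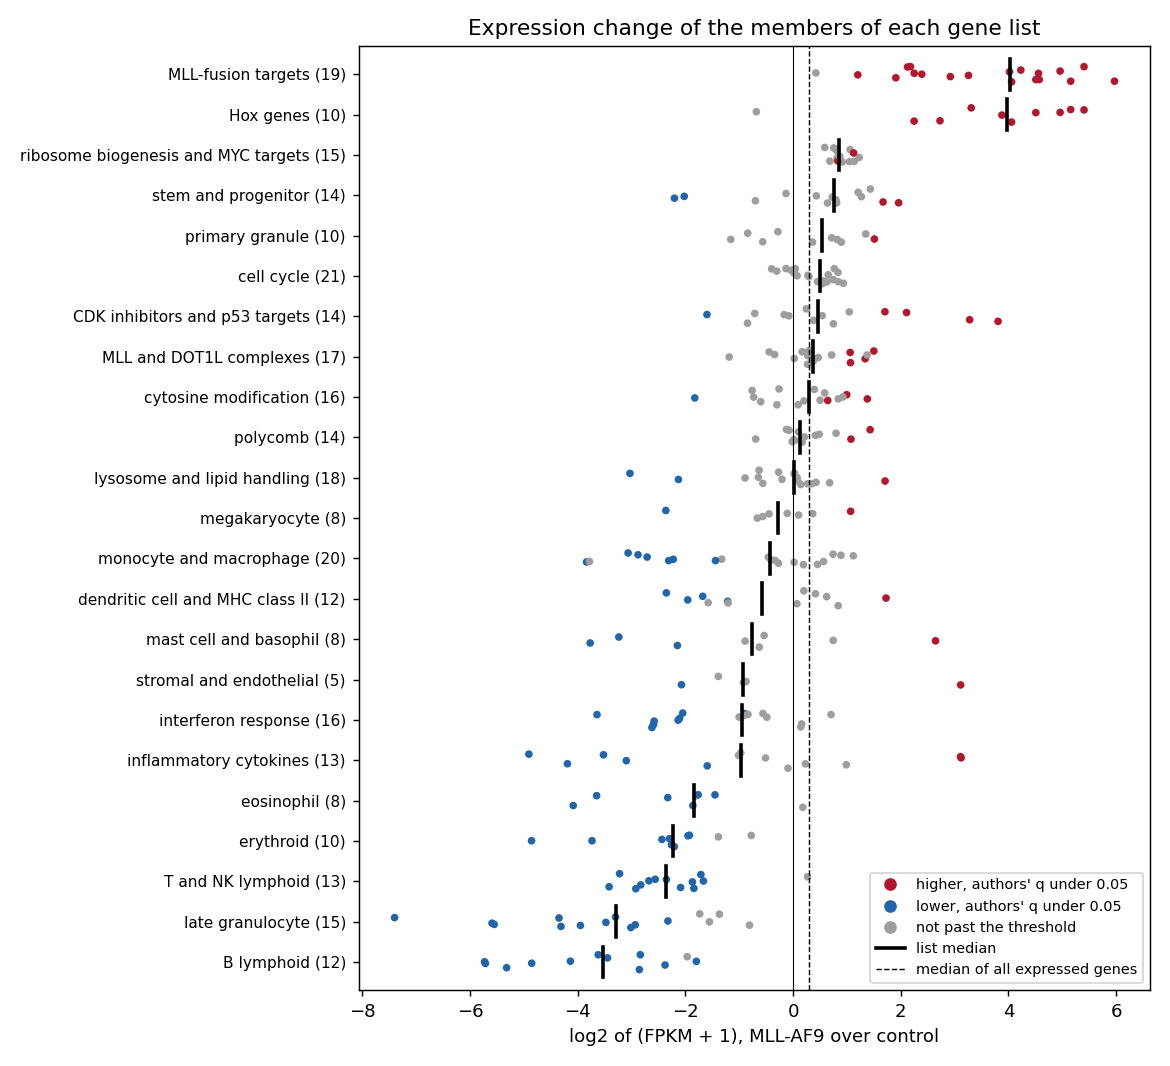
Each point is 1 expressed member of a gene list, placed by its log2 change of FPKM + 1 between the MLL-AF9 and control groups, with the number of expressed members in brackets. Black bars are list medians, which run from 4.02 for MLL-fusion targets to -3.53 for B lymphoid genes, and the dashed line is the median of all expressed genes at 0.29.

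Of the 3 TET dioxygenases, which convert 5-methylcytosine to 5hmC, Tet1 and Tet2 rose. Tet1 was at 1.76 FPKM in MLL-AF9 and 0.382 FPKM in control cells, 4.60-fold higher with q = 0.00989 in the authors' deposited table. Tet2 was 2.85-fold higher, at 18.7 against 6.56 FPKM (q = 0.0350 in the authors' deposited table). Tet3 did not pass, at 17.5 against 9.31 FPKM (q = 0.306 in the authors' deposited table). In FPKM, Tet1 was the lowest of the 3 in both groups. Of 16 expressed cytosine modification genes, 3 rose and 1 fell, or 4 and 1 when adjusted over the list alone, and their median change of 0.30, or 0.10 under quantile normalization, lay at percentile 59.6. The third gene that rose was Uhrf1, at 78.1 against 49.6 FPKM, and the gene that fell was Gadd45a, a stress-response gene, at 24.5 against 89.3 FPKM. Dnmt1, Dnmt3b and Tdg of this list were not matched and so not counted.

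Of 17 MLL and DOT1L complex genes, 4 rose and 0 fell, and when adjusted over the list alone 5 passed as higher and 1, Mllt6 at 2.35 against 6.62 FPKM, as lower (median 0.38, or 0.16 under quantile normalization, percentile 66.7). Mll1 rose 3.17-fold to 17.2 FPKM, Mllt3, which encodes AF9, rose 3.23-fold to 7.09 FPKM, and Ash2l rose 2.14-fold to 44.4 FPKM. The introduced fusion is itself built from MLL and AF9 sequence, so reads from it may not be separable from those of Mll1 and Mllt3. Of 14 polycomb genes, 2 rose and 0 fell, and 2 passed when adjusted over the list alone. These were Bmi1, 2.89-fold higher at 26.2 FPKM, and Suz12, 2.14-fold higher at 74.7 FPKM. The polycomb median of 0.13 lay at percentile 13.2 and changed sign under quantile normalization and median centring. Ezh2, Cbx6 and Pcgf2 of this list were not matched and so not counted.

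Genes of late granulocytes fell. Of 15 expressed members, 11 fell, 0 rose and 14 passed when adjusted over the list alone, with a median of -3.30 at percentile 0. Retnlg was 172-fold lower, at 51.3 against 8831 FPKM. Ltf, which encodes the secondary-granule protein lactoferrin, was 47.2-fold lower, at 127 against 6006 FPKM, and the neutrophil collagenase Mmp8 was 50.8-fold lower, at 18.4 against 937 FPKM. S100a8, a calcium-binding protein abundant in neutrophils, made up 15.4% of the summed FPKM of control cells and 2.08% of that of MLL-AF9 cells. The control sum lacks S100a9, a failed estimate listed at 0, whereas the MLL-AF9 sum holds it at 10526 FPKM. Both sums also hold 150 small RNA rows with a mean of at least 1 FPKM. These rows total 123306 FPKM in MLL-AF9 and 77948 FPKM in control cells. The 2 shares therefore have unlike totals. Primary granule genes, made earlier in the same lineage, did not follow: of 10 members 1 rose, 0 fell and 1 passed when adjusted over the list alone (median 0.54, or 0.36 under quantile normalization, percentile 92.6). The gene that rose was the transcriptional repressor Gfi1, 2.93-fold higher at 65.0 FPKM, while Mpo was listed at 627 against 927 FPKM and Elane at 1488 against 904 FPKM without passing.

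Most B lymphoid, T and NK, and erythroid genes fell. Of 12 B lymphoid genes 11 fell and 0 rose (12 adjusted over the list alone, median -3.53, or -5.36 with a pseudocount of 0.1, percentile 0), and of 13 T and NK genes 12 fell and 0 rose (12 adjusted over the list alone, median -2.35, percentile 0). Cd79a, a component of the B cell receptor, was at 2.97 against 210 FPKM, and Rag1, a recombinase of antigen receptor genes, at 0.0246 against 6.41 FPKM. Cd3d, a component of the T cell receptor complex, was 25.3-fold lower, at 0.660 against 16.7 FPKM, and the natural killer receptor Ncr1 was at 0.0758 against 2.86 FPKM. Cd79b and Nkg7 fell but remained at 28.5 and 20.4 FPKM in MLL-AF9 cells, and Il7r did not pass, at 11.1 against 9.05 FPKM. Of 10 erythroid genes 8 fell and 0 rose (9 adjusted over the list alone, median -2.23, percentile 0), among them the carbonic anhydrases Car1, 42.0-fold lower, and Car2, 15.3-fold lower. The erythroid list has 15 members. Its globin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2, and Ahsp, were not matched and so not counted. Of 8 eosinophil genes 6 fell and 0 rose (7 adjusted over the list alone, median -1.83, percentile 0), including Ccr3, at 0.0932 against 1.99 FPKM. Ear1 and Ear10 also fell, but shared reads between these ribonuclease genes are possible and were not tested.

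Other marrow lineages were divided. Of 20 monocyte and macrophage genes, 7 fell and 0 rose (8 adjusted over the list alone, median -0.44, percentile 0.07). The complement genes C1qb, 13.2-fold lower, and C1qc, 13.0-fold lower, were among them, as was Lyz1, which shares sequence with Lyz2. The receptor Csf1r was listed at 82.4 against 81.3 FPKM. Of 12 dendritic cell and MHC class II genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone, median -0.57, percentile 0.11). H2-Eb1 fell 5.22-fold, H2-Ab1 fell 3.92-fold, and Ciita, the regulator of class II genes, fell 2.96-fold, whereas the integrin Itgax rose from 7.76 to 28.0 FPKM. With a minimum mean of 5 FPKM the median of this list was 0.072. The B lymphoid genes, whose cells also carry MHC class II, fell in the same comparison. Of 8 mast cell and basophil genes, 3 fell and 1 rose (4 adjusted over the list alone, median -0.76, or -1.39 with a mean of at least 5 FPKM, percentile 0.38): the IgE receptor chain Fcer1a fell 24.9-fold and the histamine-forming enzyme Hdc 9.95-fold, while the protease Cpa3 rose 6.43-fold to 200 FPKM. Of 8 megakaryocyte genes, Pf4 fell 7.77-fold and Vwf rose 4.54-fold (2 adjusted over the list alone, median -0.28, or -0.42 under quantile normalization, percentile 3.48). Of 5 stromal and endothelial genes, Pdgfrb rose 23.4-fold to 12.1 FPKM and Thbs1 fell 4.67-fold (1 higher and 2 lower adjusted over the list alone, median -0.92, or -1.40 with a pseudocount of 0.1, percentile 0.92).

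Of 14 stem and progenitor genes, 2 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.76, percentile 99.8). Cd34 rose 4.04-fold to 78.2 FPKM and Sox4 rose from 3.28 to 12.6 FPKM. Ly6a, which encodes Sca-1, fell 4.19-fold to 22.7 FPKM, and Tal1, a regulator of blood stem and red cells, fell 11.6-fold to 0.514 FPKM. Of 21 cell cycle genes 0 rose and 0 fell, and 0 passed when adjusted over the list alone, with 1 at an unadjusted p under 0.05, although the median of 0.51 lay at percentile 98.6. Under quantile normalization that median was 0.31 and lay within the range of random lists. Of 15 ribosome biogenesis and MYC target genes, 2 rose and 0 fell (2 adjusted over the list alone, median 0.86, percentile 100): Nolc1 was 1.82-fold and Wdr12 2.31-fold higher. Of 14 CDK inhibitors and p53 targets, 4 rose and 1 fell (5 adjusted over the list alone, median 0.46, percentile 88.3). The cell cycle inhibitor Cdkn1c rose 29.7-fold to 13.0 FPKM and the pro-apoptotic gene Pmaip1 15.3-fold to 151 FPKM, while Trp53inp1 fell 3.15-fold.

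Interferon response genes were lower: of 16 expressed members 8 fell and 0 rose (8 adjusted over the list alone, median -0.96, percentile 0). Rtp4 fell from 26.5 to 1.21 FPKM, Rsad2 fell 9.80-fold and Oasl2 7.03-fold. Markers of mature granulocytes and lymphocytes were lower in the same samples. Of 13 inflammatory cytokine genes, 5 fell and 2 rose (7 adjusted over the list alone, median -0.97, percentile 0). Il1b fell 36.6-fold to 4.36 FPKM, its antagonist Il1rn 10.2-fold to 4.50 FPKM and Ccl6 18.9-fold to 25.4 FPKM, whereas the chemokines Ccl3 and Ccl4 rose, to 225 and 81.2 FPKM from 25.0 and 8.51 FPKM. Of 18 lysosome and lipid handling genes, 1 rose and 2 fell (3 adjusted over the list alone, median 0.02, percentile 11.6). Gpnmb rose 8.52-fold to 3.69 FPKM, and the lipoprotein gene Apoe fell 8.46-fold to 23.8 FPKM and the lipid receptor Cd36 12.2-fold to 0.430 FPKM. The median of this list changed sign under quantile normalization and median centring.

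Among genes reaching 5 FPKM in the higher group, the largest rises on the log2 scale included those of Stfa1 at 7.01, BC100530 at 6.96, BC117090 at 6.85, Hpgd at 6.25 and an unnamed assembled locus at 5.69. Stfa1 encodes a stefin A cysteine protease inhibitor of a family with near-identical copies, so values of single copies are uncertain. BC100530 and BC117090 rose 130-fold and 132-fold, close to the 133-fold of Stfa1. Whether these genes share reads was not tested, so they may not be independent rises. Hpgd, the prostaglandin-degrading dehydrogenase, rose 90.1-fold to 482 FPKM. The largest falls were those of Retnlg at -7.40, Cd79a at -5.73, the B lymphoid list member Vpreb3 at -5.71, and 3 unnamed assembled loci at -9.11, -6.50 and -5.81.

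**Figure D2:**
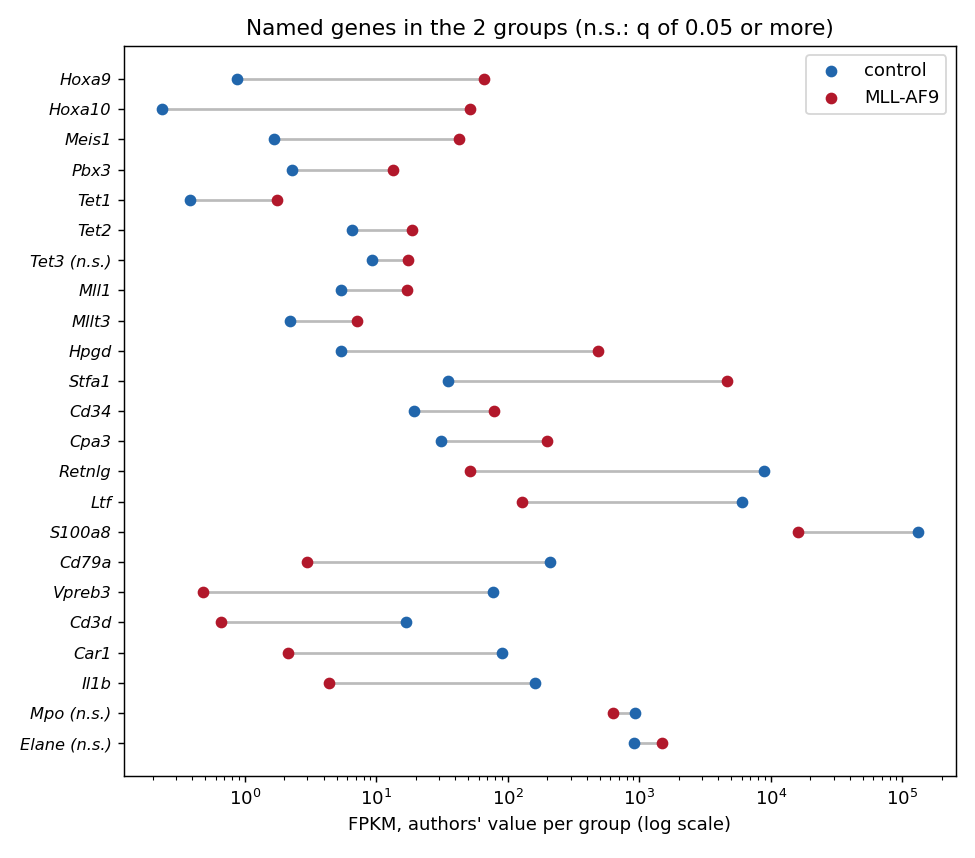
The authors' FPKM value per group, on a log axis, is shown for 23 genes, with a line joining control and MLL-AF9. Hoxa9 stands at 0.876 in control and 65.9 in MLL-AF9, and Cd79a at 210 and 2.97; genes marked n.s. have a q-value of 0.05 or more in the authors' deposited table.

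The second comparison asked where 5hmC lay in MLL-AF9 and control cells. The MLL-AF9 library had more 5hmC regions, with a lower median width. Its list held 166852 regions covering 85.8 Mb, with a median width of 441 bp, and the control list held 51286 regions covering 33.3 Mb, with a median width of 571 bp. The MLL-AF9 list was therefore 3.25 times as long and covered 2.58 times the length. With the control list's median score of 264 as a floor in both lists, an alternative chosen after seeing the data, the ratio of numbers was 2.03, although the authors' scores may not be comparable between libraries. No test was possible with 1 library per group, and the reads per library are unknown.

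Most control regions were found again in the MLL-AF9 list. Of the 51286 control regions, 41835 (81.6%, 95% Wilson interval 81.2 to 81.9, counting error only) overlapped an MLL-AF9 region by at least 1 bp, whereas control regions placed at random within their chromosomes did so for 7.33% on average over 100 shuffles. These shuffles kept neither the density of regions along a chromosome nor assembly gaps free, so overlap beyond a shared density was not tested. Of the MLL-AF9 regions, 43698 (26.2%, interval 26.0 to 26.4) overlapped a control region. This left 9451 regions only in the control list and 123154 only in the MLL-AF9 list, with 23.3 Mb shared. When the same number of top-scoring regions was taken from each list, the control share was 43.1% and the MLL-AF9 share 41.7%. Regions without an overlap had lower scores: the median was 239 against 269 for overlapping control regions, and 201 against 262 for overlapping MLL-AF9 regions. Overlapping regions had similar median widths, 589 bp in control and 574 bp in MLL-AF9. Without an overlap the median widths were 503 bp in control and 410 bp in MLL-AF9. Of the 10% of control regions with the highest scores 90.8% overlapped, compared with 76.3% of the 10% with the lowest, and for MLL-AF9 these shares were 53.3% and 12.8%.

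**Figure D3:**
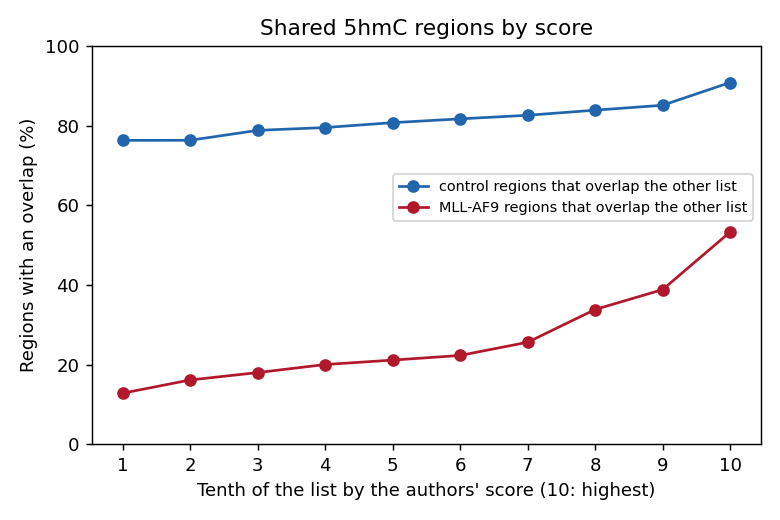
The share of 5hmC regions that overlap the other library's list by at least 1 bp is plotted for each 10% of a list, ordered by the authors' score. It runs from 76.3% to 90.8% for control regions and from 12.8% to 53.3% for MLL-AF9 regions.

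The highest-scoring regions without a counterpart lay, in mm9, on chromosome 8 from 122354553 to 122357174, chromosome 19 from 47981524 to 47984289 and chromosome 6 from 22276346 to 22278783 in the control list, with scores of 2200, 1895 and 1755. In the MLL-AF9 list they lay on chromosome 4 from 41444117 to 41446762 and on chromosome 13 from 56440862 to 56443099 and from 56209831 to 56212086, with scores of 2134, 2100 and 2048. Genes at these positions were not analysed here, since the annotation used is of another build.

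The additional MLL-AF9 regions lay near control regions more often than random positions did. Of the regions only in MLL-AF9, 58.6% lay within 10000 bp of a control region, compared with 18.3% of the same regions after 1 shuffle within chromosomes. The shuffle did not keep the density of regions along a chromosome, so nearness beyond a shared density was not tested. Across 1949 autosomal bins of 1 Mb, which are not independent replicates, the numbers of regions in the 2 libraries had a Spearman correlation of 0.93. Bins without a region in either library were left out. Each of the 19 autosomes had more regions in MLL-AF9, by 2.84 to 3.74 times. The X chromosome carried few regions in both libraries, 141 in control and 819 in MLL-AF9, which is 0.847 and 4.92 per Mb against autosome medians of 20.4 and 65.8 per Mb.

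**Figure D4:**
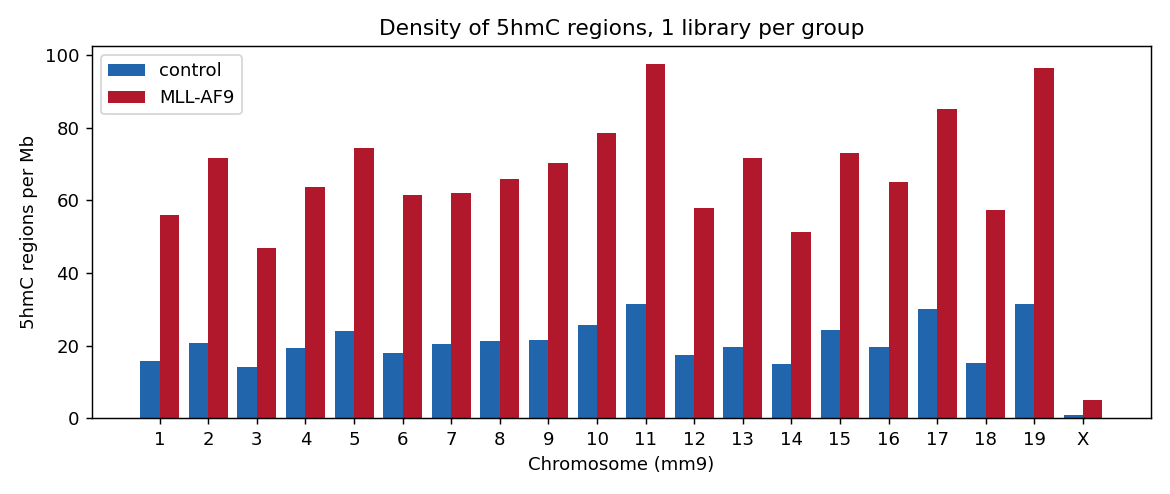
Bars give the number of 5hmC regions per Mb of each autosome and of X in the control and MLL-AF9 libraries, with 1 library per group. Autosomes hold 14.1 to 31.5 regions per Mb in control and 47.0 to 97.7 in MLL-AF9, and X holds 0.847 and 4.92.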

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

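The alternatives with recomputed q-values, named genes only, a pseudocount of 0.5 for lists, a common score floor, and centring of list medians were chosen after seeing the data. The count of 1192 called genes ranged from 843 with a mean of at least 5 FPKM to 1440 with no filter, and the share of higher calls from 47.8% to 49.7%. Rescaling cannot move the number of calls, since the q-values are the authors', and the split of 592 higher and 600 lower was the same under quantile normalization, median centring and upper-quartile scaling. Lists shifted numbered 16, 15 under quantile normalization, which lost cell cycle, and 14 of the 21 lists that could still be tested with a mean of at least 5 FPKM, which lost dendritic cell and MHC class II genes. 3 list medians changed sign: polycomb was -0.091 under quantile normalization and -0.16 under median centring, lysosome and lipid handling -0.077 and -0.27, and dendritic cell and MHC class II 0.072 with a mean of at least 5 FPKM. Median centring subtracts the shift of 0.29 of all expressed genes from every list median, so its changes of sign follow by construction. For the other settings the cause was not tested.

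For 5hmC, the ratios of numbers and length were 2.98 and 2.68 with regions within 500 bp merged, and 2.03 and 1.87 with the same score floor. With the regions above the median score of each list the length ratio was 2.64, and the ratio of numbers is fixed by construction. The shares of control and MLL-AF9 regions with an overlap were 66.9% and 20.6% with 50% reciprocal overlap, 74.5% and 22.3% with at least 50% of the control region covered, 68.1% and 21.5% with the regions above the median score of each list, and 43.1% and 41.7% with the same number of top regions. Stricter overlap, or fewer MLL-AF9 regions set against all control regions, cannot raise the control share. With the regions above the median score both lists were cut, so that share could have moved either way. The size of the drops was not explained. Library weights, other variance models, the number-series covariate, estimated correlations and leaving out a library were not run, because the table holds 1 value per group, and neither were the alternatives of the comparison of expression with 5hmC. Sequencing depth is unknown for every library, so the limits it sets are unknown too.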

Other observations

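All tests in this part except that of merged regions were chosen after the result was seen. 4 gene families were picked after their values were seen. All 7 genes picked for the stefin A family rose, from Stfa2l1, 3.64-fold higher, to Stfa1, 133-fold higher, with shared reads possible between copies. Whether these 7 are the whole family was not checked, and BC100530 and BC117090 were not among them. Of 21 immediate early genes 6 rose and 0 fell: Fosb rose 28.0-fold to 92.5 FPKM, Jun 8.46-fold to 209 FPKM and Egr1 7.59-fold to 58.6 FPKM, whereas Fos was listed at 365 against 207 FPKM and Junb at 104 against 124 FPKM without passing. Of 8 GIMAP GTPases, genes of lymphocyte survival, 7 fell, among them Gimap4, 17.3-fold lower, in a comparison in which 11 of 12 B lymphoid and 12 of 13 T and NK genes fell too. Of 5 NADPH oxidase genes 0 rose and 0 fell, with 0 at an unadjusted p under 0.05, in the authors' deposited table, the lowest unadjusted p being 0.0960 for Cybb, at 172 against 419 FPKM.

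Unnamed assembled loci made up 125 of the 1192 called genes, 81 of them higher. S100a9 was listed at 0 in control. The Y chromosome held 0 regions in the control 5hmC list and 19 in the MLL-AF9 list, 18 of which lay between 2779603 and 2901247 in mm9. At the ratio of all regions 5.84 would be counted in control. Y-linked genes were expressed in both groups in the authors' deposited table: Eif2s3y was at 78.5 FPKM in MLL-AF9 and 67.6 in control, Ddx3y at 31.8 and 17.1, and Kdm5d at 11.2 and 4.87. Xist, transcribed from the inactive X of female cells, was at 6.19 and 3.48 FPKM, so the number of X copies per cell is not known here.

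The longer MLL-AF9 5hmC list was weighed against 3 technical explanations. Cutting of regions into more pieces is argued against as the whole cause, since the ratio of numbers was still 2.98 after regions within 500 bp were merged. A deeper or better enriched MLL-AF9 library, or a shallower control library that shows part of the same sites, may account for the excess in part or in full. Regions only in MLL-AF9 had 0.767 times the median score of its overlapping regions, as depth would give. Control regions without an overlap scored lower too, at a median of 239 against 269, so this ratio cannot decide for depth. Yet 18.4% of control regions, and 9.18% of the 10% of them with the highest scores, had no counterpart. The same held for 46.7% of the 10% of MLL-AF9 regions with the highest scores. Of the highest-scoring control regions 90.8% overlapped, and how much repeat libraries of the same cells would share was not measured. Without that and without read totals, depth and a difference in 5hmC cannot be told apart. The series also holds no input library of MLL-AF9 cells, so background in that 5hmC library could not be checked.

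The scarcity of 5hmC regions on X was weighed against copy number. With 1 X copy weak regions could be lost below the calling threshold, but strong ones should stay. Per Mb, the lowest autosome still held at least 3.49 times as many regions with at least 4 times the lowest score as X held of any score, which argues against copy number alone if the score does not fall faster than the square of the signal. X-linked expressed genes had a median FPKM at least 0.802 times that of autosomal genes in both groups, so X was present and transcribed in the RNA samples. This ratio cannot decide whether an X copy was lost, since loss of an inactive copy would change it little. It also covers only genes with a mean of at least 1 FPKM, and RNA and 5hmC came from separate libraries. Read mapping, filtering by the authors and lower 5hmC on X stay open and were not tested.

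The fall of lymphoid, erythroid, eosinophil and late granulocyte genes was weighed against scaling and cell makeup. Scaling is argued against, since the median expressed gene moved the other way, by 0.29. Fewer cells of these lineages in the MLL-AF9 samples may account for it, and so may lower expression within transformed cells. Loss of cells would lower all members of a list that other cells do not express by about 1 factor. The quartile range of the log2 changes was 0.47 for erythroid, 0.97 for eosinophil and 0.99 for T and NK genes, but 2.25 for B lymphoid and 2.30 for late granulocyte genes. The 1 FPKM added to each value narrows the range of low genes: on FPKM ratios it was 0.50, 2.00, 1.32, 2.48 and 2.41 in the same order, so only the erythroid range was under 1. Of the members used, the most abundant in control cells was lower in each of the 5 lists, among them Cd79b, at 28.5 against 210 FPKM. The 5 lists were chosen because they fell. In the B lymphoid, erythroid and late granulocyte lists every member used was lower, so this check could hardly fail and decides nothing. The globin genes were not matched, so the erythroid range and its most abundant member rest on other genes. Members expressed by other cells would widen a range too, so these explanations cannot be told apart.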
